A study of Homo sapiens with 12 samples.

How the data were processed

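Total RNA of 3 human hepatocellular carcinoma cell lines was profiled by RNA sequencing with and without lactate. HLF, SNU475 and PLC/PRF/5 are established lines. Per the labels' protocols, treated cells received 20 mM lactate, supplied as lactic acid, for 24 h, RNA was extracted with TRIzol, and libraries were made with a directional kit that marks strand. Each line has 2 control and 2 lactate libraries, 12 in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

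The deposited files hold 1 gene table per library with RSEM columns. The expected counts, deposited as estimated counts that need not be whole, and the TPM values deposited beside them are RSEM's own, per the file headers. The files also hold an effective length per gene, which was used only as an alternative offset. The submitters' processing notes name FastQC, STAR, RSEM and DESeq2 without versions. They also name the mouse builds GRCm38 and mm10. All 62757 rows of each table carry human Ensembl identifiers with human symbols and 0 carry mouse identifiers, so the tables were read as human, and the human build and annotation used by the authors are not given in the sources used here. The deposited TPM values were not tested.

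The 47 rows for Y copies of pseudoautosomal genes were added to their X copies, since their sequences are near-identical, leaving 62710 genes. Expected counts were rounded to whole numbers. Genes with too few counts were removed with the default filterByExpr rule of edgeR by group, leaving 18355 genes. Library sizes were scaled with trimmed-mean (TMM) factors between 0.794 and 1.165. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust dispersions) was fitted to all 12 libraries as 6 groups, which then share 1 estimate of the spread, with 6 residual degrees of freedom. The common biological coefficient of variation was 0.26. Contrasts were the lactate effect in each line, the mean of the 3 effects with equal weights, the 2-degree-of-freedom interaction of lactate with line, and each untreated line against the mean of the other 2. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Errors of log2 fold changes are standard errors from the same fit. Levels are CPM on the scaled library sizes, as mean ± SD of 2 libraries.

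A total of 23 gene lists was fixed before the data were examined. The lists cover glycolysis, lactate and pyruvate handling, enzymes linked to lactylation, hypoxia targets, nuclear-encoded and mitochondrially encoded respiratory chain genes, cholesterol and fatty acid synthesis, the amino acid response, the unfolded protein response, DNA replication, mitosis, mesenchymal, epithelial and hepatocyte markers, inflammatory, interferon-stimulated and immediate early genes, NRF2 targets, pH regulation and acid sensing, targets of the glucose sensors MondoA and ChREBP, ribosome biogenesis, and markers of other liver cell types. Each list was compared with all other genes by camera (limma 3.58.1) with the preset inter-gene correlation of 0.01, adjusted over 92 tests, and again with a correlation estimated per list. None of the 92 tests kept an adjusted p under 0.05 with the estimated correlation, so every call of a list for lactate below rests on the preset one.

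Named genes were chosen by a rule fixed before the data were examined, among protein-coding genes with a mean of at least 2 CPM. For the mean effect it takes the 10 higher and the 10 lower genes with the largest fold among calls with the same sign in the 3 lines. For the interaction it takes the 6 smallest p, for each untreated line the 5 highest folds, and for each list up to 4 members with the smallest p. A fixed set of glycolysis and lactate genes is always reported. The rule would also have taken the 5 higher and 5 lower calls of each line, but there were none. The 2 further genes it names for untreated SNU475 and 1 for untreated PLC/PRF/5 are not reported here. Lineage list members are reported for the untreated lines as well. Any other gene was named after its values were seen.

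The check for pairing correlated the deviations of same-numbered libraries from their group means. It gave 0.101 in HLF, 0.446 in SNU475 and 0.132 in PLC/PRF/5, all above the limit of 0.1 set beforehand, although HLF only just. By that limit same-numbered libraries counted as paired in every line, but the main fit has no block for replicate number. With 2 libraries in a group the deviations mirror each other, so swapping the numbers within a single group would turn the sign of the correlation. The numbers come from the sample titles and no label says what they share. For PLC/PRF/5 the libraries numbered 2 in the titles carry number 3 in the deposited names, so their number is less certain. The fit with line and replicate number as blocks is an alternative, and its values are given beside results that it moves. It gave 1268 calls for the mean effect where the main fit gave 77. In HLF, SNU475 and PLC/PRF/5 it gave 3, 46 and 121 calls where the main fit gave none.

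Other alternatives were DESeq2 size factors, the DESeq2 1.42.0 test, limma-voom, no filter, a filter of at least 1 CPM in at least 6 libraries, effective-length offsets, each line fitted alone, and each library left out in turn. A GC correction, a fit without mitochondrial genes and a fit without both SNU475 libraries numbered 2 were added after seeing the data. In the leave-one-out fits, the lone library of a group is assumed to vary like the other groups. Gene positions and biotypes come from the GENCODE 29 annotation of GRCh38, matched on Ensembl identifiers for 17665 of the 18355 genes, and the files give no positions.

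Library totals ran from 16530000 to 22190000 expected counts, so that 1 CPM stands for 14.7 to 25.8 counts. Over the 2 libraries of a group, a count of 0 allows up to 3 counts, or 0.0658 to 0.0973 CPM, for counting error only. List medians at bounds use folds of the pooled CPM of each group, with this floor. They therefore differ from fitted medians even where no gene is at 0. On simulated counts for the same 18355 genes, the test recovered 70 of 100 genes changed 2-fold and 95 of 100 changed 4-fold for the mean effect. For single lines it recovered 22, 14 and 15 of 100 genes changed 2-fold in HLF, SNU475 and PLC/PRF/5, and 81, 82 and 77 of 100 genes changed 4-fold. False calls were 8 of 173 for the mean effect. For HLF, SNU475 and PLC/PRF/5 they were 4 of 107, 11 of 107 and 4 of 96. The changed genes were drawn from those with higher mean counts, and each gene had the same spread in every line. The rates therefore do not cover genes near 0 counts or differences in spread between the lines.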

Results

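The transcriptomes of HLF, SNU475 and PLC/PRF/5 cells were compared with and without 20 mM lactate for 24 h, with 2 libraries for each of the 6 combinations. The study's title concerns feedback of lactate on glycolysis through a lactyl mark on histone H4, and the comparisons ask which genes differ with lactate in each line, on average, and between lines. Totals lay between 16530000 and 22190000 counts per library. The first 2 principal components, with 50% and 38.1% of the variance, separated the lines. Replicates correlated across genes at 0.95 (SNU475 lactate) to 0.988 (PLC/PRF/5), against at most 0.812 between libraries of different lines. The chi-square per degree of freedom between replicates was 11.4 or more, so the 2 libraries of a group were not copies of each other.

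The share of mitochondrially encoded transcripts varied within groups. It was 9.52% and 3.39% in the HLF controls and 5.49% and 3.93% in the HLF lactate libraries. In SNU475 it was 8% and 8.5% in the control and lactate libraries numbered 1, and 15.05% and 13.88% in those numbered 2. In PLC/PRF/5 it stayed between 6.21% and 7.08%. The third principal component separated the SNU475 libraries by number, at -56 and -51.2 for number 1 against 14.8 and 87.5 for number 2. The fourth, with 2.4% of the variance, was positive in every control and negative in every lactate library.

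Averaged over the 3 lines, TXNIP and PDK4 were among the genes that rose with lactate, and ATF5 and LANCL2 among those that fell. TXNIP, which encodes an inhibitor of glucose uptake and of thioredoxin, rose by 1.98 ± 0.29 on the log2 scale (SE, adjusted p = 0.0269, edgeR). Its level went from 16.8 ± 2.09 to 53.8 ± 21.8 CPM in HLF and from 97.9 ± 11 to 583 ± 354 CPM in SNU475 (SD, n = 2 each). In PLC/PRF/5 it was low in both conditions, at 0.375 ± 0.108 and 1.24 ± 0.543 CPM, but above the floors of 0.0793 and 0.0658 CPM. PDK4, a kinase that shuts pyruvate dehydrogenase, rose by 1.84 ± 0.25 (adjusted p = 0.0269). Its levels were 80.25 ± 21 and 135 ± 28.7 CPM in PLC/PRF/5 and 3.92 ± 0.661 and 8.66 ± 2.13 CPM in SNU475, while in HLF only 3 control and 45 lactate counts were seen. TXNIP lies on chromosome 1 at 145992435 to 145996600 and PDK4 on chromosome 7 at 95583499 to 95596491 (GRCh38).

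Among the other named genes that rose were the kinase gene LMTK3 (1.83 ± 0.28), the phospholipid transfer protein gene PLTP (1.81 ± 0.33), MAPT, which encodes the microtubule protein tau (1.74 ± 0.26), and the splicing-related gene SRRM3 (2.08 ± 0.31). For PLTP the PLC/PRF/5 controls held 2 counts. The homeobox gene PRRX2 rose as well (2.22 ± 0.39), with 1 control count in HLF. CPT1C, a brain-type carnitine palmitoyltransferase, ADAMTS7, a secreted metalloprotease, and the readthrough gene CHKB-CPT1B also passed the test. Their fitted mean folds rest partly on a control group at 0 counts. CPT1C was at least 4.98-fold higher with lactate in PLC/PRF/5, ADAMTS7 at least 3.59-fold higher in HLF, and CHKB-CPT1B at least 11-fold higher in SNU475. CHKB-CPT1B shares its sequence with both of its parent genes, so its counts are uncertain.

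ATF5, a transcription factor of the integrated stress response, fell by 1.06 on the log2 scale (SE 0.145, adjusted p = 0.0269). Its level went from 40.1 ± 4.34 to 17.5 ± 6.74 CPM in HLF, from 60.8 ± 2.93 to 18.6 ± 2.90 CPM in SNU475 and from 107.9 ± 8.66 to 89.0 ± 9.25 CPM in PLC/PRF/5. ATF5 lies on chromosome 19 at 49928702 to 49933935. LANCL2 fell in similar proportion in the 3 lines (-0.999 ± 0.275, -1.113 ± 0.276 and -0.996 ± 0.274). The others were the serpin gene SERPINB8 (-1.09 ± 0.18), TRMT61A, part of a tRNA methyltransferase (-1.11 ± 0.20), FAM13B (-1.03 ± 0.17), the mitochondrial ATPase gene ATAD3B (-0.95 ± 0.15), the lysosomal disease gene CLN6 (-0.90 ± 0.15), SURF2 (-0.89 ± 0.16) and PTDSS1, a phosphatidylserine synthase (-0.79 ± 0.14). SPNS2, an exporter of sphingosine-1-phosphate, passed the test too, with 24 control and 1 lactate counts in HLF and 24.9 ± 4.59 against 13.4 ± 1.94 CPM in PLC/PRF/5. Its adjusted p was 0.0761 without both SNU475 libraries numbered 2.

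**Figure D1:**
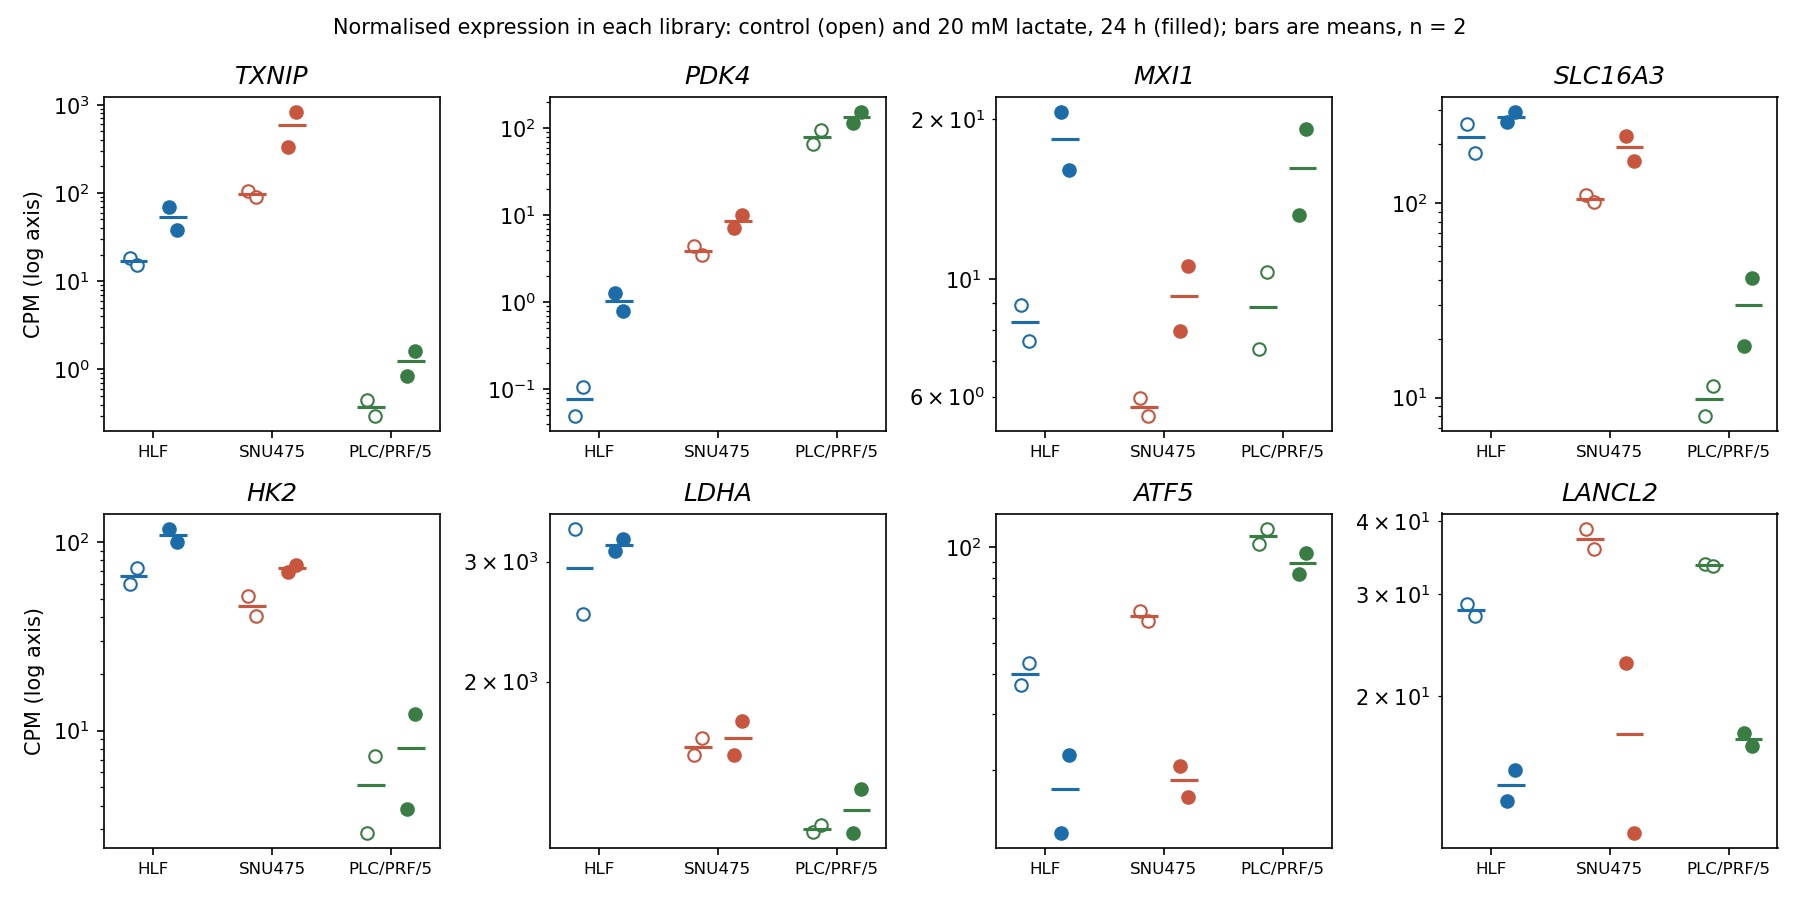
Normalised expression (CPM, log axis) of 8 genes in each of the 12 libraries, with open circles for control, filled circles for lactate and bars at group means (n = 2). TXNIP and PDK4 lie higher with lactate in all 3 lines, ATF5 and LANCL2 lower, while LDHA differs by 0.11, 0.04 and 0.09 on the log2 scale in HLF, SNU475 and PLC/PRF/5.

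In all, 77 of 18355 genes passed an adjusted p of 0.05 for the mean effect (edgeR), 56 higher and 21 lower, and 2903 had an unadjusted p under 0.05 where 918 are expected by chance. Over all 18355 genes, 37.94% had the same sign in the 3 lines, where chance gives 25%. For 6.1% both lactate libraries lay beyond both control libraries in every line, one way, where chance gives 0.93%. Among the 77 calls these held for 75 and 70. The 77 were chosen on the same libraries, so their agreement is no independent support. The count depends on the fit: it was 1268 with the replicate block, which kept all 77, and 892 by DESeq2, 16 by limma-voom and 17 with effective-length offsets. Leaving out single libraries gave 0 to 1493, with 0 for either HLF control, for HLF lactate replicate 1 and for any PLC/PRF/5 library, 24 for HLF lactate replicate 2, 4 and 149 for SNU475 control replicates 2 and 1, and 300 and 1493 for SNU475 lactate replicates 2 and 1.

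The glycolysis list, the subject of the study's title, was higher with lactate as a group, but no member passed the test over all genes. Of its 20 genes, 17 had a positive mean effect, with a median log2 fold change of 0.257, and camera placed the list above other genes (adjusted p = 0.00129). Its adjusted p was 0.664 with an estimated correlation. Adjusted over the list alone, 2 genes were higher, the brain-type isoenzymes ALDOC (1.86 ± 0.40) and ENO2 (0.75 ± 0.21). ALDOC varied widely in PLC/PRF/5, at 2.70 ± 2.23 CPM without and 20.7 ± 18.2 CPM with lactate. The list also passed in each line, with medians of 0.137 in HLF, 0.171 in SNU475 and 0.171 in PLC/PRF/5 (adjusted p = 0.0409, 0.0313 and 0.0288). With an estimated correlation these 3 had unadjusted p = 0.404, 0.371 and 0.37. Without both SNU475 libraries numbered 2, the mean effect kept its call (adjusted p = 0.0432) and the 3 lines did not (medians 0.152, 0.112 and 0.163, adjusted p = 0.0714, 0.401 and 0.131). When single libraries were left out, the medians went down to 0.003 in HLF and 0.019 in SNU475, with 2 calls lost in each, and to -0.047 in PLC/PRF/5, with 1 call lost and 1 reversed in direction (adjusted p = 0.843).

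The abundant enzymes of the lower pathway differed little. LDHA, the main lactate dehydrogenase gene, had a mean log2 fold change of 0.08 ± 0.12, ENO1 -0.13 ± 0.12 and PKM -0.07 ± 0.13, with adjusted p of 0.818, 0.667 and 0.882. HK2, the inducible hexokinase, had 0.67 ± 0.27 (adjusted p = 0.253, or 0.0109 with the replicate block), PGK1 0.33 ± 0.13 (adjusted p = 0.252) and SLC2A1, the main glucose transporter, 0.24 ± 0.17 (adjusted p = 0.55). PFKFB3 (0.06 ± 0.14) and LDHB (-0.16 ± 0.21) were within 1 SE of 0. Both genes changed sign when single libraries were left out.

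**Figure D2:**
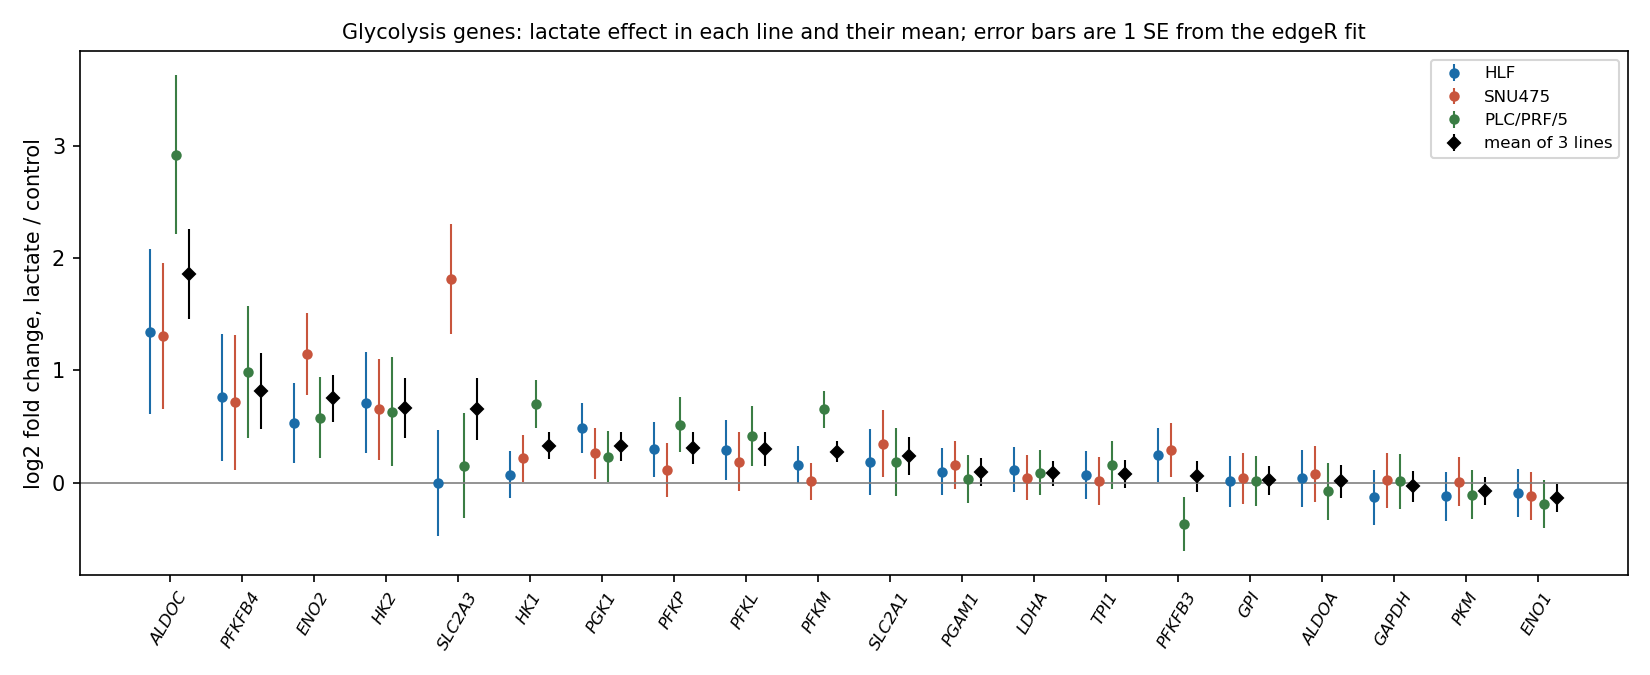
Log2 fold change (lactate over control) of the 20 glycolysis genes in each line (circles) and averaged over lines (diamonds), with bars of 1 SE. The upper genes ALDOC, ENO2 and HK2 have means of 1.86, 0.75 and 0.67, and LDHA, PKM and ENO1 lie near 0.

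Genes that handle lactate and pyruvate were higher as a list, with 15 of 20 tested genes positive (median 0.115, or 0.116 with 1 gene at its bound, camera adjusted p = 0.0127, adjusted p = 0.58 with an estimated correlation). Leaving out single libraries gave medians from 0.072 to 0.213, with 1 call lost. PDK4 passed over all genes. Adjusted over the list alone, 5 were higher, PDK4 with SLC16A3, PDK1, PDK3 and PCK2. SLC16A3, the lactate exporter MCT4, had 0.94 ± 0.19 (adjusted p = 0.0608, or 0.00312 with the replicate block), and in PLC/PRF/5 its level was 9.78 ± 2.43 CPM without and 29.7 ± 16.1 CPM with lactate. SLC16A1, which encodes MCT1, had 0.07 ± 0.14 and the lactate receptor gene HCAR1 0.26 ± 0.48, near the detection limit in HLF and PLC/PRF/5. Among 18 enzymes linked to adding or removing lactyl groups, 9 were positive and 9 negative (median -0.028, camera adjusted p = 0.578). EP300, a proposed lactyl writer, had -0.06 ± 0.20. Adjusted over the list alone, the acetyltransferase gene KAT2A was lower (-0.63 ± 0.12).

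Targets of the hypoxia pathway gave the strongest list result. Of 20 genes, 19 were positive, with a median of 0.653. On pooled folds the median was 0.587, with 1 gene that has an empty group in HLF held at its bound. Pooled folds differ from fitted ones by themselves. In PLC/PRF/5, with 0 genes at a bound, they gave a median of 0.769 against 0.805. Camera gave the list an adjusted p of 3.72e-10. With an estimated correlation its p was 0.0262 before and 0.58 after adjustment. None passed over all genes, and 10 were higher when adjusted over the list alone. They include MXI1, a MYC antagonist (0.90 ± 0.18), the mitophagy receptor BNIP3L (0.61 ± 0.12), the collagen crosslinking enzyme LOX (1.08 ± 0.27), P4HA1 (0.69 ± 0.18) and DDIT4, an mTORC1 inhibitor (1.53 ± 0.39). Medians were 0.649 in HLF (0.631 with that bound), 0.582 in SNU475 and 0.805 in PLC/PRF/5, each passing camera (adjusted p = 5.85e-07, 3.28e-04 and 2.33e-06). When single libraries were left out, the medians ran from 0.424 to 1.036 in HLF, 0.455 to 0.703 in SNU475 and 0.246 to 1.008 in PLC/PRF/5, with no call lost. The SNU475 median was 0.403 and its adjusted p 0.113 without both of its libraries numbered 2.

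The 9 targets of MondoA and ChREBP, which sense glucose metabolites, were higher as a list (median 0.407, or 0.387 with 2 genes at their bounds, 8 positive, camera adjusted p = 5.05e-04, adjusted p = 0.58 with an estimated correlation). TXNIP passed over all genes, and the related arrestin gene ARRDC4 (1.08 ± 0.31) and MLXIPL, which encodes ChREBP, were higher when adjusted over the list alone. MLXIPL had 0 control and 4 lactate counts in HLF, a bound of 1.2-fold, and 4.5 and 9.8 CPM in PLC/PRF/5.

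Genes of DNA replication were lower. All 19 had a negative mean effect (median -0.319, camera adjusted p = 8.14e-09, adjusted p = 0.58 with an estimated correlation). None passed over all genes and 8 were lower when adjusted over the list alone, among them GINS2 (-0.53 ± 0.13), MCM5 (-0.48 ± 0.12), CDC6 (-0.52 ± 0.14) and PCNA (-0.38 ± 0.11). The 19 mitosis genes were split, with 9 positive and 10 negative (median -0.004, adjusted p = 0.545). The mitosis list, without both SNU475 libraries numbered 2, passed as lower (median -0.145, adjusted p = 0.00342). Ribosome biogenesis was lower in 15 of 18 genes (median -0.298, adjusted p = 4.69e-05, 0.664 with an estimated correlation). Adjusted over the list alone, 4 of them were lower, namely RRP12 (-0.54 ± 0.12), NOP56 (-0.48 ± 0.12), NOP58 (-0.50 ± 0.13) and RRS1 (-0.72 ± 0.23). NRF2 targets, which respond to oxidative stress, were negative in 14 of 18 (median -0.112, or -0.116 with 1 gene at its bound, adjusted p = 0.00398, 0.58 with an estimated correlation), led by HMOX1, a haem oxygenase (-0.80 ± 0.15), OSGIN1 (-0.97 ± 0.19) and SRXN1 (-0.45 ± 0.13), the 3 that were lower adjusted over the list alone. The NRF2 median ran from -0.175 to -0.04 when single libraries were left out, with no call lost.

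The 13 mitochondrially encoded mRNAs were lower as a list (12 negative, median -0.421, camera adjusted p = 0.0172, 0.768 with an estimated correlation), while replicate controls of HLF differed in mitochondrial share by more than the 2 conditions. Without HLF control replicate 1 the median was -0.102 (adjusted p = 0.66). Interferon-stimulated genes (17 of 19 positive, median 0.387, or 0.253 with 4 genes at their bounds, adjusted p = 0.0283) and epithelial markers (10 of 13 positive, median 0.475, adjusted p = 0.0353) passed camera but not with an estimated correlation (adjusted p = 0.768 and 0.58), and no interferon gene passed singly. Each of these 2 calls was lost in 4 of the 12 fits that leave out 1 library, with medians from 0.102 to 0.868 for interferon-stimulated and 0.276 to 1.156 for epithelial genes, and so was that of mitochondrially encoded mRNAs (-0.632 to -0.102). Adjusted over the list alone, the epithelial gene CLDN4 was higher (0.96 ± 0.27). Without both SNU475 libraries numbered 2, the calls of lactate and pyruvate handling, mitochondrially encoded mRNAs, interferon and epithelial genes were lost (adjusted p = 0.224, 0.164, 0.0951 and 0.0994), in a fit with 2 fewer libraries, while the medians were 0.151, -0.354, 0.322 and 0.579. The other lists did not pass for the mean effect in the main fit.

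Their medians and camera adjusted p were 0.000 and 0.785 for 25 nuclear-encoded respiratory chain genes, 0.058 and 0.861 for 22 genes of cholesterol synthesis, 0.007 and 0.802 for 12 of fatty acid synthesis, and 0.064 and 0.642 for 16 of the unfolded protein response. They were 0.147 and 0.625 for 21 genes of the amino acid response, 0.126 and 0.141 for 15 mesenchymal, 0.204 and 0.751 for 20 hepatocyte, -0.111 and 0.226 for 19 inflammatory and 0.242 and 0.0709 for 15 immediate early genes. They were 0.189 and 0.239 for 13 genes of pH regulation and 0.271 and 0.438 for 16 markers of other liver cell types. With genes that have an empty group held at their bounds, the last 6 medians were 0.163, 0.158, -0.098, 0.236, 0.175 and 0.297. With the replicate block the mesenchymal list passed (median 0.14, adjusted p = 0.0273, or adjusted p = 0.472 with an estimated correlation). Over 23 alternatives, immediate early genes gained a call in 7, mesenchymal in 5, inflammatory in 3 and mitosis genes in 2. Most of these gains came from fits that leave out 1 library. For the amino acid response and cholesterol synthesis the test pointed down although median and mean were above 0. Within the amino acid list ATF5 passed over all genes, and the transporter genes SLC7A5 (-0.56 ± 0.14) and SLC3A2 (-0.60 ± 0.12) were lower when adjusted over the list alone. In the pH list the acid-sensing channel gene ASIC1 passed over all genes (1.13 ± 0.21, adjusted p = 0.0446). Adjusted over the list alone, GPR4, a proton-sensing receptor (1.62 ± 0.40), and the bicarbonate transporter gene SLC4A7 (0.64 ± 0.18) were higher and SLC4A2 (-0.72 ± 0.25) and ATP6V0D1 (-0.38 ± 0.14) lower.

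**Figure D3:**
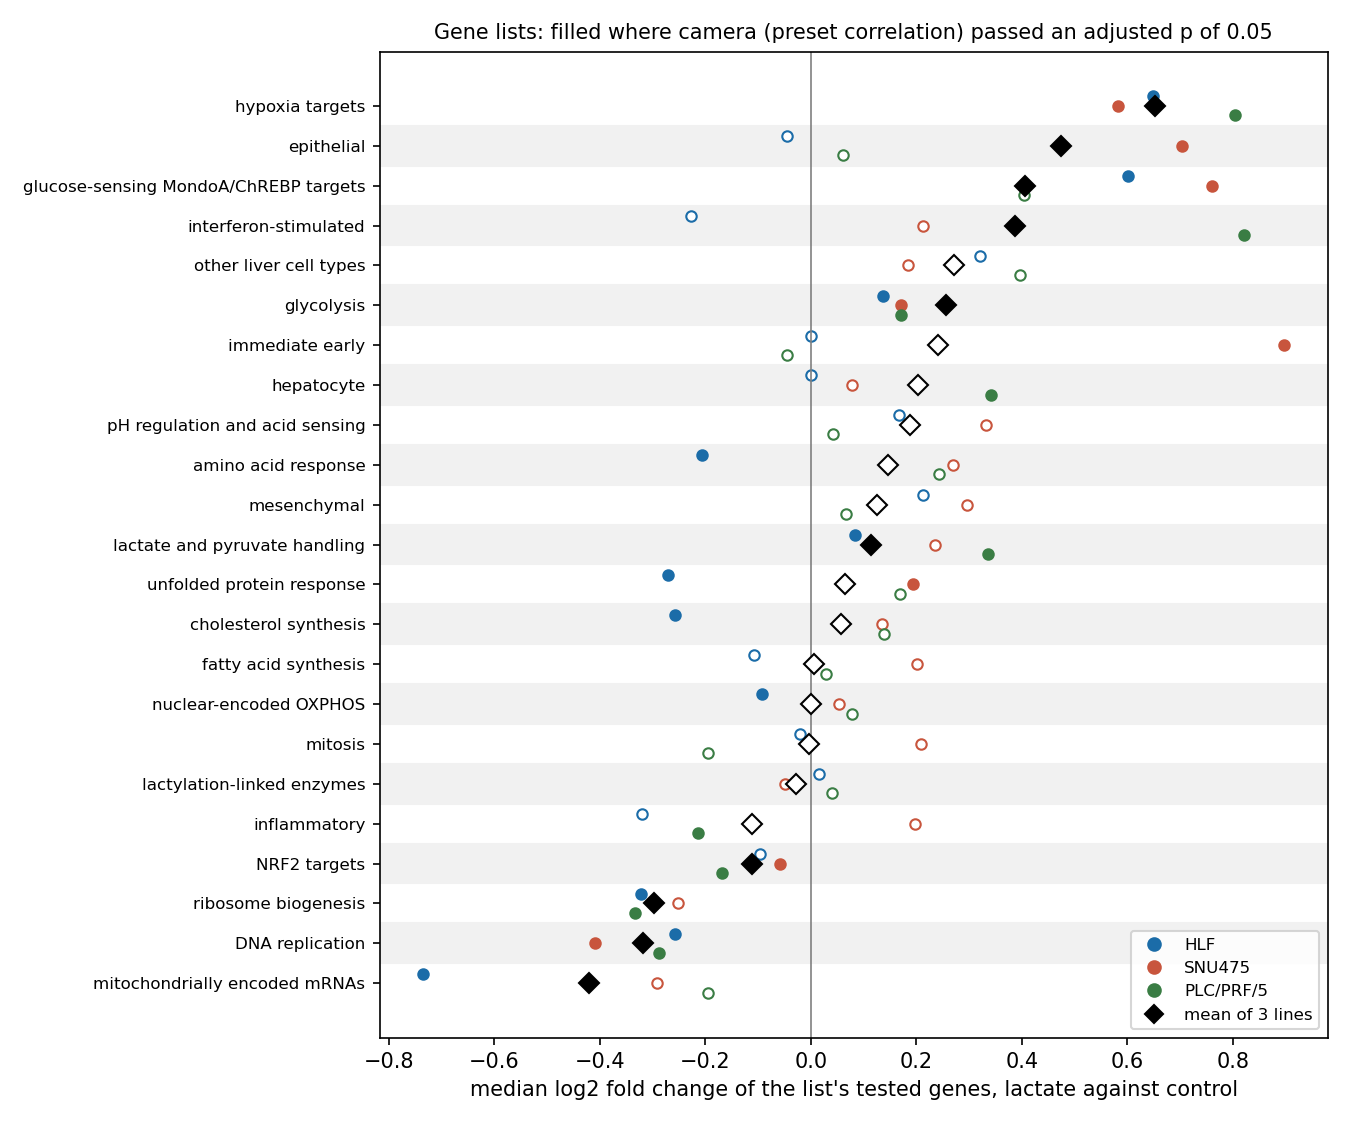
Median log2 fold change (lactate over control) of each gene list in HLF, SNU475 and PLC/PRF/5 (circles) and for the mean effect (diamonds), filled where camera with the preset correlation passed. Hypoxia targets lie highest for the mean effect, at 0.653, and DNA replication at -0.319 lies below 0 in all 3 lines.

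Within single lines, no gene passed an adjusted p of 0.05 (edgeR), so no gene is named for a line alone by the rule. The genes with an unadjusted p under 0.05 numbered 1152 in HLF, 2127 in SNU475 and 1087 in PLC/PRF/5, against 918 expected. The smallest adjusted p were 0.405 for CORO2A in HLF, 0.23 for ATF5 in SNU475 and 0.0518 for COL6A2, a collagen VI chain, in PLC/PRF/5. Other fits made calls. Fitted alone, PLC/PRF/5 had 569 and HLF 1. Without the low-count filter there were 111, 414 and 188 in HLF, SNU475 and PLC/PRF/5. The main fit shares 1 estimate of the spread among the lines. Control and lactate replicates differed more in SNU475 (SD of the log2 difference 0.85 and 1.07) than in PLC/PRF/5 (0.53 and 0.51). The replicate block gave 3, 46 and 121 genes in HLF, SNU475 and PLC/PRF/5, of which 2, 33 and 103 were higher, DESeq2 gave 36, 202 and 86, and limma-voom gave 0 in each. HLF had 39 and PLC/PRF/5 138 without both SNU475 libraries numbered 2. In SNU475, leaving out lactate replicate 1 gave 1788 genes and leaving out control replicate 1 gave 1. In PLC/PRF/5 the count was 18 without SNU475 lactate replicate 1, 19 without replicate 2 and 1 without either SNU475 control.

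Some lists passed camera in single lines. In SNU475, 14 of 15 immediate early genes were positive (median 0.898, adjusted p = 7.87e-05), with 6 higher when adjusted over the list alone, including ATF3 (2.21 ± 0.65) and DUSP1 (2.10 ± 0.54). Epithelial markers (median 0.704, adjusted p = 0.00112) and the unfolded protein response (0.193, adjusted p = 0.0402) also passed there. In PLC/PRF/5, 17 of 19 interferon-stimulated genes were positive (median 0.822, or 0.781 with 3 genes at their bounds, adjusted p = 3.1e-05), led by IFIT1 (1.92 ± 0.39), and hepatocyte genes (0.341, adjusted p = 0.0326) passed as higher and inflammatory genes as lower (-0.213, or -0.269 with 4 genes at their bounds, adjusted p = 0.0424). In HLF, 20 of 22 cholesterol synthesis genes were negative (median -0.257, adjusted p = 3.45e-04), led by EBP (-0.86 ± 0.26), and the unfolded protein response (-0.270, adjusted p = 0.0166), amino acid response (-0.206, adjusted p = 0.0332) and nuclear-encoded respiratory chain genes (-0.093, adjusted p = 0.0313) were lower. With an estimated correlation the smallest unadjusted p of these lists was 0.0322, for the epithelial list in SNU475, and the smallest adjusted p was 0.58. The amino acid call in HLF was lost with the replicate block (adjusted p = 0.0996), as was that of NRF2 targets in SNU475 (0.0743 against 0.0472). Without both SNU475 libraries numbered 2, the immediate early median was 0.187 (adjusted p = 0.172), and 4 calls were lost at similar medians. These were hepatocyte (0.333, adjusted p = 0.0951) and inflammatory genes (-0.221, adjusted p = 0.127) in PLC/PRF/5 and the amino acid response (-0.19, adjusted p = 0.117) and respiratory chain (-0.077, adjusted p = 0.0544) in HLF, in a fit with 2 fewer libraries.

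Many of these calls rest on single libraries. In SNU475, leaving out 1 library moved the epithelial median between -0.072 and 1.246 and that of the unfolded protein response between 0.072 and 0.425, with 2 calls lost in each, and that of immediate early genes between 0.099 and 1.371, with 1 lost. In PLC/PRF/5 the hepatocyte median ran from -0.072 to 0.704, with 1 call lost and 1 reversed in direction (adjusted p = 0.617, without lactate replicate 2), and the inflammatory median from -0.442 to 0.059, with 2 lost. The interferon call there was kept throughout (0.604 to 1.032). In HLF, medians ran from -0.414 to -0.186 for cholesterol synthesis and -0.299 to -0.091 for the amino acid response, with 1 call lost in each, and from -0.446 to -0.003 for the unfolded protein response, with 2 lost. The respiratory chain list in HLF ran from -0.259 to 0.052, with 1 call lost and 1 reversed in direction (adjusted p = 0.681, without control replicate 1).

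Of the lists with a call for the mean effect, glycolysis, hypoxia targets and DNA replication passed in all 3 lines. DNA replication was lower in HLF, SNU475 and PLC/PRF/5 (medians -0.258, -0.41 and -0.287, adjusted p = 0.00117, 3.22e-06 and 3.78e-06). Ribosome biogenesis was lower in HLF (-0.321, adjusted p = 3.44e-04) and PLC/PRF/5 (-0.334, adjusted p = 2.14e-04), with 0.0513 in SNU475, or 0.0164 with the replicate block. NRF2 targets were lower in PLC/PRF/5 (-0.169, adjusted p = 5.05e-04) and SNU475 (-0.058). MondoA and ChREBP targets were higher in SNU475 (0.761, or 0.749 with 1 gene at its bound, adjusted p = 4.99e-05) and HLF (0.602, or 0.258 with 2 genes at their bounds, adjusted p = 0.00398). Lactate and pyruvate handling was higher in HLF (0.084, adjusted p = 0.0353) and PLC/PRF/5 (0.336, adjusted p = 0.0332), and mitochondrially encoded mRNAs were lower in HLF (-0.735, adjusted p = 0.00115). Without HLF control replicate 1, which had 9.52% mitochondrial transcripts, the direction of that last list was reversed (0.34, adjusted p = 0.0738). With an estimated correlation the smallest adjusted p of these was 0.58. When both SNU475 libraries numbered 2 were left out, lactate and pyruvate handling in HLF (0.098, adjusted p = 0.278) and PLC/PRF/5 (0.329, adjusted p = 0.162) and the MondoA list in SNU475 (0.226, adjusted p = 0.0579) lost their calls. Leaving out single libraries lost 2 calls each for DNA replication (-0.399 to -0.097), ribosome biogenesis (-0.51 to -0.127) and lactate and pyruvate handling (0.027 to 0.221) in HLF and for the last list in PLC/PRF/5 (0.139 to 0.343), 1 for the MondoA list in HLF (0.283 to 0.62) and 3 for NRF2 targets in SNU475 (-0.228 to -0.015). The MondoA median in SNU475 ran from 0.179 to 1.14, with no call lost. With the replicate block, mesenchymal markers passed as higher in HLF and SNU475 (adjusted p = 0.0335 and 0.00702), markers of other liver cell types in HLF and PLC/PRF/5 (0.0309 and 0.0239), and mitosis genes as lower in PLC/PRF/5 (0.0184). With an estimated correlation and the block, their adjusted p was 0.717 for mitosis and 0.472 for the others, and 0.496 for ribosome biogenesis in SNU475.

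Whether the lines responded differently was tested by the interaction. No gene passed (edgeR, smallest adjusted p = 1), and 644 genes had an unadjusted p under 0.05, fewer than the 918 expected. The simulated effects were the same in every line, so the power of the interaction test is unknown. The lack of calls therefore does not show that the lines responded alike. DESeq2 called 9 genes, limma-voom 0 and the replicate block 6, and leaving out SNU475 lactate replicate 1 gave 203. The smallest p were for SLC7A8, an amino acid transporter gene with 0 control and 26 lactate counts in HLF (at least 7.77-fold higher) and 10.5 ± 2.02 against 5.64 ± 0.299 CPM in SNU475, and for SARM1, EFEMP2, COL6A2, EHD2 and NOSTRIN. SARM1, an NAD-cleaving enzyme gene, had 0.88 ± 0.27, 0.36 ± 0.33 and -1.18 ± 0.22 in HLF, SNU475 and PLC/PRF/5, EFEMP2 had -0.07 ± 0.33, 1.15 ± 0.39 and 3.61 ± 0.51, and NOSTRIN had 15 control and 2 lactate counts in HLF and 1.32 ± 0.34 in PLC/PRF/5. COL6A2 had a log2 fold change of 1.86 ± 0.22 in PLC/PRF/5, 0.57 ± 0.19 in SNU475 and 0.20 ± 0.19 in HLF, and the membrane-bending gene EHD2 1.49 ± 0.20, 0.22 ± 0.18 and 0.09 ± 0.18.

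Fold changes of the lines were weakly related across genes, which are not independent replicates. The lines share no control library. Across 18355 genes, Pearson and Spearman correlations were 0.128 and 0.298 for HLF and SNU475, 0.112 and 0.252 for HLF and PLC/PRF/5, and 0.108 and 0.206 for SNU475 and PLC/PRF/5. In the more highly expressed part of the genes, above the median level, the Pearson correlations were 0.483, 0.325 and 0.302. Genes higher in both lines at an unadjusted p under 0.05 numbered 170, 131 and 161 for the 3 pairs, where independent lists would share 38.5, 27.1 and 52.9, and genes lower in both numbered 150, 58 and 60 against 28.6, 7.8 and 13.5.

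The untreated lines differed widely. PLC/PRF/5 expressed liver genes that the other lines lacked. All 20 hepatocyte markers were higher in it (camera adjusted p = 7.21e-28), with a median log2 difference of 8.06 when the 11 genes at 0 counts in a line were held at their bound. With an estimated correlation the camera p was 0.00373 before adjustment, and no call is made from it. Fetal liver marker AFP stood at 2349 ± 839 CPM against 1.99 ± 0.129 in SNU475. APOB, the apolipoprotein of secreted lipoproteins, was at least 7500-fold, the glutathione peroxidase gene GPX2 at least 3610-fold, CALB1 at least 3330-fold and the amino acid transporter gene SLC6A19 at least 3070-fold higher in PLC/PRF/5 than in either other line. Mesenchymal markers were higher in SNU475 (13 of 15 genes, median 1.973) and HLF (10 of 15, median 1.468) and lower in PLC/PRF/5 (12 of 15, median -3.614), each with 1 gene at its bound, with camera adjusted p of 4.94e-10, 0.00654 and 3.5e-10. With an estimated correlation the unadjusted p were 0.00868, 0.0852 and 0.0065. That of HLF did not pass even before adjustment, and no call is made from these values. VIM, which encodes vimentin, was at 5767 ± 1440, 5420 ± 1220 and 443 ± 106 CPM in HLF, SNU475 and PLC/PRF/5.

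SNU475 also had high NRF2 targets, with 17 of 18 genes above the other lines (median 2.291, camera adjusted p = 4.29e-19, adjusted p = 0.0124 with an estimated correlation), while 16 were lower in HLF (median -1.47, adjusted p = 0.0191 with an estimated correlation). AKR1B10 stood at 2250 ± 543 CPM in SNU475, 83.5 ± 21.2 in PLC/PRF/5 and 1 count in HLF. The BMP antagonist gene GREM1 was at least 10400-fold and the cardiac actin gene ACTC1 at least 1090-fold higher in SNU475 than in either other line, and IGFBP5 reached 483 CPM there against 0.156 in PLC/PRF/5. In HLF, 15 of 19 interferon-stimulated genes were higher (median 3 with 4 genes at their bounds, camera adjusted p = 6.4e-07, unadjusted p = 0.136 with an estimated correlation). The collagenase gene MMP1 was at 3733 ± 1510 CPM in HLF and 15.9 ± 1.46 in SNU475, PTPRD was at least 1000-fold and SMIM10 at least 252-fold higher in HLF than in the other lines, and GPR15 and PAGE5 stood at 87.2 and 52.6 CPM with at most 3 counts elsewhere. Of the 18355 genes, 7059 differed in HLF, 7921 in SNU475 and 8433 in PLC/PRF/5 from the mean of the other lines (edgeR), and 3698, 4753 and 4420 of these were higher. Without HLF control replicate 1 the HLF count was 4626, and without PLC/PRF/5 control replicate 2 that of PLC/PRF/5 was 5492.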

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

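The GC tests below were chosen after the related results were seen, while the tests on splits and replicate spread were set beforehand.

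Several lists had lactate effects that differed between lines by camera on the difference itself, adjusted over the 3 pairs of lines, and none of these calls held with an estimated correlation (smallest unadjusted p = 0.0599). Median differences of HLF minus SNU475 were -0.645 for cholesterol synthesis, -0.531 for the unfolded protein response, -0.811 for immediate early genes, -0.589 for epithelial markers and -0.167 for nuclear-encoded respiratory chain genes. For HLF minus PLC/PRF/5 they were -0.573 for cholesterol synthesis, -0.411 for the unfolded protein response, -0.278 for the amino acid response, -0.949 for interferon-stimulated genes and -0.229 for nuclear-encoded respiratory chain genes. For SNU475 minus PLC/PRF/5 they were 0.909 for immediate early genes, 0.761 for MondoA and ChREBP targets, 0.498 for epithelial markers and -0.772 for interferon-stimulated genes. No single gene of the interaction passed.

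Cholesterol synthesis genes were lower with lactate in HLF and not in the other lines. A trend on GC content is argued against as the whole cause, since the correction left the difference from PLC/PRF/5 at 0.91 of its size. The spread of the whole list between libraries stays open, as its mean level differed by 0.346 between the HLF controls, more than the lactate effect of -0.298, although both HLF lactate libraries lay below both controls, and 1 of the 12 fits that leave out a library lost the call. A response of HLF itself to lactate therefore remains an untested hypothesis.

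Chance in how the libraries were divided is an unlikely source of the 77 calls of the mean effect. Of 100 splits of the 4 libraries of each line into 2 and 2, 3 gave as many calls, the real one included. The highest of the others gave 567, and both splits above the real one divided SNU475 by replicate number, as 33 of the 100 did. These 2 splits, with 567 and 120 calls, also kept the real grouping with its sign turned, in 2 lines and 1 line. Many of the other splits hold the real or turned grouping in at least 1 line, so they are not free of the lactate difference. All splits treat the 4 libraries of a line as separate cultures, which no label states. If the 2 libraries of a group shared a culture, the splits cannot test differences between cultures. Among the 31 splits that part all 6 pairs of same-numbered libraries, the highest of the others gave 1, and the other 69 part fewer pairs. No split was fitted with the replicate block, so the 1268 calls of the blocked fit have no split counts beside them. The called genes were rich in GC, at a median of 59.9% for the higher and 57.9% for the lower genes against 48.4% for all, but 70 of the 77 stayed past the threshold after a GC correction, so a GC trend across libraries is not enough to explain them. An effect of lactate, or of the acid in which it was given, are possible explanations that the design cannot separate.

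Hypoxia targets were higher with lactate in all 3 lines. A GC trend is argued against, since after the correction the smallest ratio of a line's median effect to its former size was 0.9. Spread of the whole list between libraries could still contribute, since its mean level differed by 0.805 between the PLC/PRF/5 lactate libraries, more than the smallest lactate effect of 0.604, in HLF. Both lactate libraries of hypoxia targets lay above both controls in every line. In all, 4 of the 23 lists lay apart one way in every line (3 above, and NRF2 targets below). Chance gives 0.21 in either direction. Within same-numbered pairs, a count made after seeing the data, all 6 hypoxia differences were positive (0.41 to 0.934). Of the 23 lists, 10 kept one sign in all 6 pairs where 0.72 are expected. They include markers of other liver cell types (0.042 to 0.542), epithelial and mesenchymal genes above. DNA replication, NRF2 targets and ribosome biogenesis are among them below. These levels were not compared with other genes, so the counts cannot decide whether spread of the hypoxia list contributes.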

How the results depend on the processing

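The GC corrections, the fit without mitochondrial genes and the fit without both SNU475 libraries numbered 2 were chosen after seeing the data, and the other alternatives before the data were examined. Directions held better than calls. The 20 genes named for the mean effect kept their sign in all 23 alternatives (1 of them was not tested with the stricter filter). They were chosen for large folds of the same sign in every line, so refits of the same libraries could hardly turn that sign. Of these genes, 13 lost their call with effective-length offsets and 15 with limma-voom. Their calls were also mostly lost when single libraries were left out. All 77 calls were shared by DESeq2, the replicate block, DESeq2 size factors and the fit without a filter. Values across the alternatives were followed for genes named for the mean effect, the interaction, the untreated lines and the set always reported. Of these 1173 values, 932 stayed on the same side of the threshold with the same sign. A call was lost by 203 and gained by 26, and 12 changed sign. Interaction values have no sign and were judged by the threshold alone. The untreated genes, chosen for the highest folds, kept every call. Genes named only as list members were not followed. Of 1171 list values, 1006 stayed on the same side of the threshold with the same test direction. A call was lost by 125 and gained by 17, and 23 turned direction. These list values cover every list for the mean effect, but in single lines only lists called in the main fit. Gains in single lines were therefore not counted.

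Calls of the mean effect numbered 77, but 892 with DESeq2, 922 without a filter, 126 with a stricter filter, 1268 with the replicate block, 17 with effective-length offsets, 16 with limma-voom, 147 with the GC correction, 1410 with the GC correction and replicate block, 530 without both SNU475 libraries numbered 2 (75 of the 77 shared), and 0 to 1493 leaving out 1 library. Calls in HLF numbered 36 with DESeq2, 111 without a filter, 3 with the replicate block and with GC and block, 39 without the SNU475 libraries and 1 with the line fitted alone. In SNU475 they numbered 202, 414, 46 and 43 for DESeq2, no filter, the block and GC with block, and 0 to 1788 leaving out 1 library. In PLC/PRF/5 they numbered 86, 188, 121 and 103 for the same 4, 1 with effective-length offsets and without mitochondrial genes, 138 without the SNU475 libraries, 569 with the line fitted alone, and 0 to 19 leaving out 1 library. The interaction gave 9, 136, 6 and 3 for the same 4 and 0 to 203 leaving out 1 library. Untreated counts ran from 4626 to 8462 in HLF and 5492 to 9776 in PLC/PRF/5 when leaving out 1 library. The cause was not tested, but leaving out libraries changes the number of samples and the filter the genes tested.

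The glycolysis list kept its call for the mean effect in every alternative (median 0.153 to 0.322) except the estimated correlation, where the median is 0.257 and the adjusted p 0.664. For lists, the replicate block changed no calls other than those given in the report. With it the amino acid list had its test direction turned (median 0.093). Of 38 gene values followed with the block, 2 gained a call, those of SLC16A3 and HK2 for the mean effect. Genes named only as list members were not followed with it.

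Changes of sign, or for lists of the test's direction, concerned values without a call, with 4 exceptions. PFKFB3 was -0.02763 with effective-length offsets and -0.009443 without the SNU475 libraries, SLC16A1 was -0.02554 there, and the fatty acid list was 0.052 there and -0.028 with GC and block. Leaving out 1 library, PFKFB3 ran from -0.04278 to 0.186, SLC16A1 from -0.07183 to 0.1836, EP300 from -0.2955 to 0.09979, HCAR1 from -0.2026 to 0.9212 and LDHB from -0.3568 to 0.1768. List medians ran from -0.053 to 0.069 for nuclear-encoded respiratory chain genes, -0.122 to 0.123 for cholesterol synthesis, -0.021 to 0.135 for the unfolded protein response, 0.041 to 0.412 for hepatocyte genes, -0.061 to 0.147 for fatty acid synthesis, -0.206 to 0.172 for mitosis and 0.01 to 0.253 for the amino acid response. The 4 called lists were respiratory chain (-0.259 to 0.052) and mitochondrially encoded (-1.337 to 0.34) genes in HLF and glycolysis (-0.047 to 0.397) and hepatocyte genes (-0.072 to 0.704) in PLC/PRF/5. With 2 libraries per group, single-line changes of 2-fold were mostly out of reach of the main fit in simulation. It recovered 14 to 22 of 100 genes with higher counts, given the same spread in every line.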

Other observations

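The genes and lists named in this part were chosen after their values were seen. Further genes past the threshold for the mean effect were SEMA6B, a semaphorin (0.98 ± 0.12), CORO2A, an actin-binding coronin (1.37 ± 0.18), and EFEMP2, an elastic fibre protein gene (1.56 ± 0.24), all with an adjusted p of 0.0269, although EFEMP2 was at -0.07 ± 0.33 in HLF. EHD2 (0.60 ± 0.11) and COL6A2 (0.88 ± 0.12) also passed.

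For the hepatocyte list the lactate median in PLC/PRF/5 was 0.341, while its median gap to the other lines was 8.06. PLC/PRF/5 also had the lowest TXNIP, at 0.375 CPM against 97.9 in SNU475, and SNU475 had little LDHB, at 5.49 CPM against 865 in PLC/PRF/5 and 278 in HLF. Glycolysis genes were higher in untreated HLF (12 of 20, median 0.722) and lower in PLC/PRF/5 (12 of 20, median -0.811), with camera adjusted p of 0.0185 and 0.0138 and unadjusted p of 0.329 and 0.31 with an estimated correlation.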
